A study of Mus musculus with 8 samples.

How the data were processed

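Samples were assigned to genotypes from the sample titles, with 4 arrays of PMCA4 wild-type and 4 of PMCA4 knockout cells. Per the labels' protocols, total RNA was extracted with a PicoPure kit, converted to biotin-labelled cRNA with an Illumina amplification kit and hybridised to Illumina mouse bead arrays. The deposited table of non-normalized values holds a signal intensity for each of 25697 probes on each array. Between 28.42% and 29.69% of these intensities were below 0, so background had already been subtracted before they were deposited. The scanner software is not given in the sources used here. The same deposited table holds a detection p-value per probe and array, which per the file headers belongs to that signal. A second deposited table holds log2 values. Every column of it has the median 6.05 and the same sorted values to within 0.000531, and its ranks equal those of the intensities within each array, so these values were quantile normalized. The software behind it is not given in the sources used here, and the table was used as an alternative only. No column of per-sample values was left out.

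Intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which infers the negative control mean and spread from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were tested, 12040 in number. Differences between genotypes were fitted with lmFit and eBayes without a block, and p-values were adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05 and no minimum fold. Log2 changes are knockout minus wild type, and standard errors are those of the moderated fit. Adjusted p-values of single genes come from this limma fit.

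Probes were named through the annotation of the array platform, with symbols updated by gene identifier to the GRCm38.p6 gene table. Of all probes, 23978 had 1 gene symbol, 0 had several and 1719 had none. The gene table matched 23962 of them. It was used for names and for which genes neighbour each other. Of the tested probes, 684 had no symbol and 390 of these passed the threshold. A gene was represented by its tested probe with the highest mean log2 value over the 8 arrays, which gave 8302 genes. Where a probe was not above background (detection p of 0.05 or more) on every array of one genotype, the fold is given as a lower bound, the mean of the brighter group against the mean over the other group of the higher of 2 values per array: the probe's own value and the lowest value among detected probes. Of the called genes, 168 were not above background on any wild-type array and 112 on any knockout array.

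The genes named were fixed by a rule before the data were examined. They are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose 4 arrays of one genotype lay on one side of the other 4, together with Atp2b1, Atp2b2, Atp2b3, Atp2b4, Rgs16, Ccnd1, Cdkn1a, Myc, Acta2 and Myh11, and up to 4 members past the threshold with the largest change from each gene list. In all, 29 gene lists of pathways and cell types were written before the data were examined, and 26 had at least 3 tested members. These were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists, beside camera with an estimated correlation and fry. The mean of a list per array, centred per gene, was compared with an exact permutation test of 4 arrays against 4. Genes within 25 Mb of Atp2b4 were compared with all others by Fisher's exact test.

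The fit was tested on simulated data made from the spread of these arrays for the knockout comparison over 8302 genes. It called 12% of 50 genes changed by 0.25 on the log2 scale, 70% of 50 changed by 0.5, and 100% of 50 changed by 1 and of 50 changed by 2, with 9 of 8077 unchanged genes called. A list shifted by -0.5 was called and 0 of 25 unshifted lists were. The simulated noise was drawn independently for each probe, so genes of a list were not correlated and the preset correlation was not tested. Far fewer genes were changed than were called in the real data, so these recovery rates need not hold there. The alternatives tried were no background correction, normexp with an offset of 50, median scaling, cyclic loess, the deposited log2 table, no filter on dim probes, a detection p under 0.01, an intensity trend with robust spread, array weights, the replicate number as a block, the mean of probes per gene, other thresholds and windows, an estimated correlation, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.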

Results

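Gene expression was profiled in primary vascular smooth muscle cells of the mouse carotid artery. The cells carried either the wild-type or the knockout genotype of PMCA4, a plasma membrane calcium pump that exports calcium from the cell and is encoded by Atp2b4. All cells were on a C57bl6 background and came from males. They were synchronised with respect to serum, stimulated with serum and PDGF-BB (a platelet-derived growth factor that drives smooth muscle proliferation), stained with the DNA dye Hoechst and flow sorted for the early G1 population. Total RNA of each sample was hybridised to 1 Illumina bead array, with 4 arrays per genotype and 25697 probes per array. Between 11697 and 11987 probes per array had a detection p under 0.05. The number of arrays limits the precision of every value given here. The labels do not say whether arrays of a genotype came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

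Atp2b4 itself did not differ between the groups by more than the spread between arrays. Its only probe above background gave log2 intensities of 6.72, 6.90, 7.05 and 6.89 in wild type and of 7.17, 6.99, 6.56 and 7.07 in knockout. The group means were 6.89 ± 0.14 and 6.95 ± 0.27 (SD, n = 4 each, exact two-sided permutation p = 0.7143). The log2 difference was 0.06, with a 95% confidence interval from -0.23 to 0.34. The other 2 Atp2b4 probes were not above background on any array. The labels do not say which part of the gene was deleted, and a probe outside that part does not check the genotype, so the direction of every change below rests on the labels of the arrays. Among the other plasma membrane calcium pumps, Atp2b1 had a log2 difference of 0.15 (adjusted p = 0.0974), and Atp2b2 and Atp2b3 were not above background. The list of these pumps thus had 2 members tested of 4, and 0 passed.

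The comparison of the genotypes asked which transcripts differ between early G1 smooth muscle cells labelled PMCA4 knockout and wild type. Genes of DNA replication and mitosis were lower in the arrays labelled knockout, at a median of 2.61-fold and 2.86-fold, and genes of cholesterol and fatty acid synthesis were lower at a median of 1.54-fold. Contractile genes of smooth muscle, genes of the extracellular matrix and markers of adventitial fibroblasts were higher, at medians of 1.66-fold, 1.42-fold and 4.13-fold. These sizes are those of members that passed the filter on dim probes. Without it, which adds members near background, the medians were 1.78-fold lower for mitosis and 1.41-fold, 1.21-fold and 1.67-fold higher for the contractile, matrix and fibroblast lists. These 6 lists passed camera with a preset correlation, and none of them passed with an estimated one (adjusted p from 0.0555 to 0.1112). The largest single rise was that of Dcn, which encodes the matrix proteoglycan decorin, at 109-fold, and the largest fall was that of Ano1, which encodes a calcium-activated chloride channel, at 24.3-fold, with Ano1 detected on only 2 of 4 knockout arrays. Rgs16, a regulator of G protein signalling fixed for report before the data were examined, was 52.8-fold higher. Its log2 change ranged from 4.76 to 5.79 over the processing alternatives.

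Of 8302 genes tested with limma, 4781 passed an adjusted p of 0.05 (57.59%), 2233 higher and 2548 lower in knockout. By the fitted change, 486 of these were higher and 447 lower by at least 2-fold, and 58 were higher and 18 lower by at least 8-fold. With genes not above background in one genotype counted at their lower bound, a recount chosen after the data were seen, these numbers were 434, 408, 48 and 14. All 4 arrays of one genotype lay on one side of all 4 of the other for 53.47% of the genes tested, against 2.86% given by chance. At the level of probes, 3168 were higher and 3609 lower of 12040 tested. Among 1286 called genes with several tested probes, the probes of 417 differed in call or direction, and 21 of them had probes called in opposite directions. The first principal component held 87.26% of the variance and separated the genotypes, with scores from -41.17 to -36.52 in wild type and from 38.14 to 39.6 in knockout.

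The 12 genes with the largest rises by the fitted change were led by Dcn, Casp1, Ccl8 and Rgs16. Dcn went from a log2 intensity of 7.37 ± 0.37 in wild type to 14.14 ± 0.07 in knockout (SD, n = 4 each), a log2 change of 6.77 with a standard error of 0.15 (limma adjusted p = 3.62e-10). Casp1, the protease that matures interleukin-1 beta, was not above background on any wild-type array and was at least 58.7-fold higher in knockout. Its smallest fitted log2 change among the processing alternatives was 4.89, which is less than that bound. Ccl8, a chemokine, was detected on 1 wild-type array only and was 56.7-fold higher by the fit, or 49.7-fold with each undetected array set to its lowest detected value, a limit chosen after the data were seen. Rgs16 went from 6.08 ± 0.16 to 11.80 ± 0.05 (SD, n = 4 each, limma adjusted p = 4.08e-11). Actg2, the smooth muscle gamma actin, was at least 32.1-fold higher. Acta1, the skeletal alpha actin, was 33.2-fold higher and was detected on 3 wild-type arrays. Pdpn (podoplanin) rose by 5.13 on the log2 scale, and Igfbp6 and Serpinf1 rose 31.0-fold and 30.4-fold. Lce1f, detected on 3 wild-type arrays, and Serpinb2 rose 28.6-fold and 26.4-fold, and Serpinb6c was at least 17.2-fold higher.

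The 12 genes with the largest falls were led by Ano1, Eln and Serpinb1a. Ano1 fell from 10.39 ± 0.17 to 5.79 ± 0.32 (SD, n = 4 each, limma adjusted p = 4.88e-09), or 22.5-fold with undetected arrays at their lowest detected value. Eln, which encodes elastin, fell from 10.30 ± 0.14 to 5.98 ± 0.14 (SD, n = 4 each, limma adjusted p = 2.83e-10), or 19.9-fold. Serpinb1a, a serine protease inhibitor, was 17.5-fold lower. Itga3, an integrin subunit, was 15.6-fold lower, and Ramp3, which modifies the calcitonin receptor-like receptor, was detected on 1 knockout array only and was 14.9-fold lower by the fit, or 12.4-fold with undetected arrays at that value. Angptl7 and Smoc1 were 14.8-fold and 11.9-fold lower, and Luzp2, detected on 2 knockout arrays, was 9.88-fold lower. The homeobox genes Shox2 and Lhx9 were not above background on any knockout array and were at least 9.91-fold and 4.99-fold lower. Their weakest fitted log2 changes among the processing alternatives were -2.42 and -2.09, smaller falls than these bounds. Twistnb and Chn2 were likewise not above background in knockout and were at least 6.83-fold and 5.46-fold lower.

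**Figure D1:**
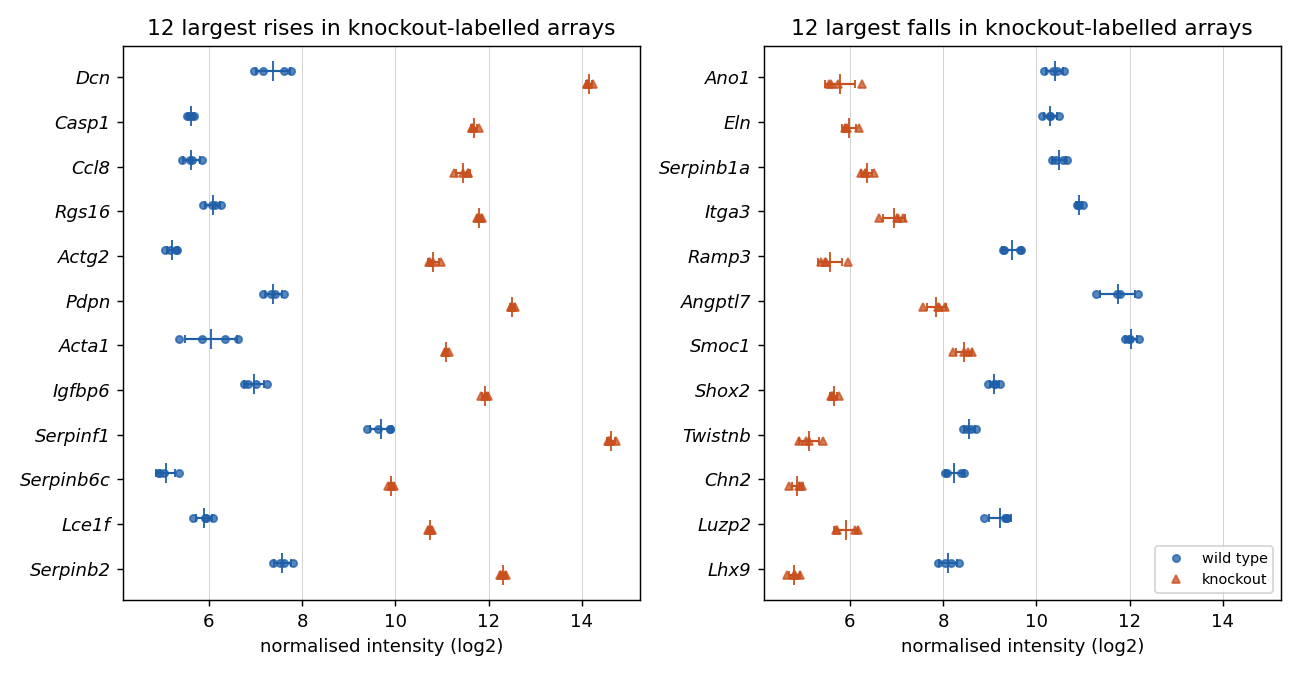
Normalised log2 intensity (horizontal axis) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) among called genes, in 4 wild-type arrays (circles) and 4 knockout-labelled arrays (triangles). Vertical ticks are group means and horizontal bars are 1 SD. Dcn has means of 7.37 in wild type and 14.14 in knockout. No gene shown has overlapping groups, which was a condition of the choice.

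Genes of the cell cycle were lower as a group. All 35 tested members of the list of S phase and DNA replication fell, with a median log2 change of -1.38 (camera adjusted p = 1.48e-15, and adjusted p = 0.1112 with an estimated correlation). Tk1, thymidine kinase of the nucleotide salvage pathway, was 5.41-fold lower, and Mcm6, a subunit of the replicative helicase, was 4.88-fold lower. Lig1, the replicative DNA ligase, was 4.56-fold lower by its brightest probe, and its 4 tested probes did not all pass. Chaf1b was 4.39-fold lower. Of 22 genes of G2 and mitosis, 21 fell and 0 rose, with a median of -1.52 (camera adjusted p = 1.21e-10, and adjusted p = 0.1112 with an estimated correlation), or -0.83 over 37 members without the filter on dim probes. Top2a, Kif23 and Kif2c were 4.58-fold, 4.47-fold and 4.11-fold lower, Kif23 being detected on 2 and Kif2c on 3 knockout arrays, and Kif11 was not above background in knockout and was at least 3.34-fold lower. Every tested replication gene was still detected on all 4 knockout arrays. Of the 22 tested mitosis genes, 17 were detected on all 4 knockout arrays and 22 on all 4 wild-type arrays.

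Regulators of G1 moved in both directions. Of 26 tested, 6 rose, 13 fell and 7 did not pass (median -0.25, camera adjusted p = 0.1506). The mean per array of this list differed by -0.33 on the log2 scale, or by -0.28 without Rbl1, its member of largest change (exact two-sided permutation p = 0.02857 for both). The pocket protein Rbl1 and the transcription factor E2f2 fell 3.19-fold and 2.99-fold, E2f2 being detected on 1 knockout array (2.54-fold with undetected arrays at their lowest detected value), and the CDK inhibitor Cdkn1b fell 2.70-fold. Cdkn1c was not above background in knockout and was at least 1.79-fold lower. Cdkn1a, the CDK inhibitor p21, rose 1.35-fold (adjusted p = 0.00103). Ccnd1, cyclin D1, had a log2 difference of 0.10 (adjusted p = 0.186), and Myc had one of -0.16 (adjusted p = 0.364), so neither passed.

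Genes of lipid, ribosome and mitochondrial function were lower by smaller amounts. Of 25 genes of cholesterol and fatty acid synthesis, 23 fell and 0 rose (median -0.62, camera adjusted p = 9.43e-08, and adjusted p = 0.066 with an estimated correlation). Elovl6, a fatty acid elongase, was 3.07-fold lower, Scd2 was 2.14-fold lower and Mvd was 2.09-fold lower. Of 47 ribosomal protein genes, 30 fell and 0 rose (median -0.23, camera adjusted p = 0.000105, and adjusted p = 0.0843 with an estimated correlation), among them Rps15a and Rpl21 by 1.79-fold and 1.60-fold. Of 53 genes of the respiratory chain, 25 fell and 3 rose (median -0.17, camera adjusted p = 0.00958, and adjusted p = 0.2285 with an estimated correlation), among them the complex I genes Ndufs6 and Ndufs8 by 1.45-fold and 1.42-fold.

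Contractile and matrix genes were higher as groups. Of 21 contractile genes, 16 rose and 3 fell (median 0.73, camera adjusted p = 6.02e-06, and adjusted p = 0.066 with an estimated correlation). Mylk, the myosin light chain kinase, was not above background in wild type and was at least 11.7-fold higher. Aoc3, detected on 3 wild-type arrays, and Mustn1 rose 7.47-fold and 5.56-fold. Acta2, the smooth muscle alpha actin, rose by 0.83 on the log2 scale at its brightest probe, which lay among the 11 brightest probes on each knockout array, and by 2.13 to 2.79 at its other 3 probes. Myh11, the smooth muscle myosin heavy chain, was not above background in wild type and was at least 1.98-fold higher. Of 40 matrix genes, 23 rose and 4 fell (median 0.51, camera adjusted p = 5.64e-05, and adjusted p = 0.0555 with an estimated correlation), and the median was 0.27 over 49 members without the filter on dim probes. Lum (lumican) was at least 11.5-fold higher and Tnc (tenascin C) was 6.84-fold higher, while Eln was lower.

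Some, but not all, lists of markers of other cell types that a carotid artery culture could hold passed camera with a preset correlation as well. Of 14 markers of adventitial fibroblasts and mesenchymal progenitors, 12 rose and 1 fell (median 2.04, camera adjusted p = 4.11e-06, and adjusted p = 0.066 with an estimated correlation). Over the 21 members on the array, without the filter on dim probes, the median was 0.74 (camera adjusted p = 4.72e-08). Dpt rose by 3.46 on the log2 scale and Sfrp1 rose 10.1-fold, beside Igfbp6 and Lum. All 4 Schwann cell and neuron markers tested rose (median 0.91, camera adjusted p = 0.0163, and adjusted p = 0.2494 with an estimated correlation), Uchl1 by 2.75-fold and Ncam1 by 2.73-fold. The rise of Cnp, by 0.25 on the log2 scale (adjusted p = 0.0359), was past the threshold in 13 of 19 alternatives and was lost in 6, without the filter on dim probes and without wild-type replicate 1, 2 or 4 or knockout replicate 1 or 3 (adjusted p from 0.0593 to 0.0863). Of 4 skeletal muscle markers, 3 rose (median 1.40, camera adjusted p = 0.00601, and adjusted p = 0.2153 with an estimated correlation), led by Acta1, with Tnnt1 at least 2.85-fold higher. Both calls ended without the filter on dim probes, where the Schwann cell and neuron list had a median of -0.0036 (camera adjusted p = 0.4213) and the skeletal muscle list one of 0.049 (camera adjusted p = 0.1375). Under normexp with an offset of 50 the skeletal muscle median was 0.83. The remaining cell type lists did not pass. Of 7 leukocyte markers, 4 rose and 1 fell (median 0.79, camera adjusted p = 0.0911). This median was 0.0072 over 25 members without the filter on dim probes. It was from -0.13 to -0.029 without any 1 knockout array, where 5 members passed the filter. That filter still asked for 4 arrays, so members above background in knockout only, such as Lyz2 and Cd3e, could not pass there. The lower medians therefore do not show that the rise rests on single arrays. Lyz1, detected on 3 wild-type arrays, rose 8.74-fold and its near-identical copy Lyz2 at least 2.40-fold, Cd3e was at least 1.87-fold higher and Cd14 was 3.34-fold lower. Of 5 endothelial markers, 2 rose and 2 fell, with Flt1 1.54-fold higher and Plvap 1.49-fold lower (camera adjusted p = 0.7642). Of 4 chondrocyte and osteoblast markers, 3 rose (median 0.71, camera adjusted p = 0.0749), with Bglap at least 2.39-fold higher, and the median was 0.054 over 14 members without the filter on dim probes. The adipocyte list had 2 members tested, of which Pparg fell 2.37-fold, and the red blood cell list had 1, Hbb-bh1, with a log2 difference of 0.25 (adjusted p = 0.144). The 3 tested genes of the sex chromosomes did not pass (camera adjusted p = 0.9303).

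**Figure D2:**
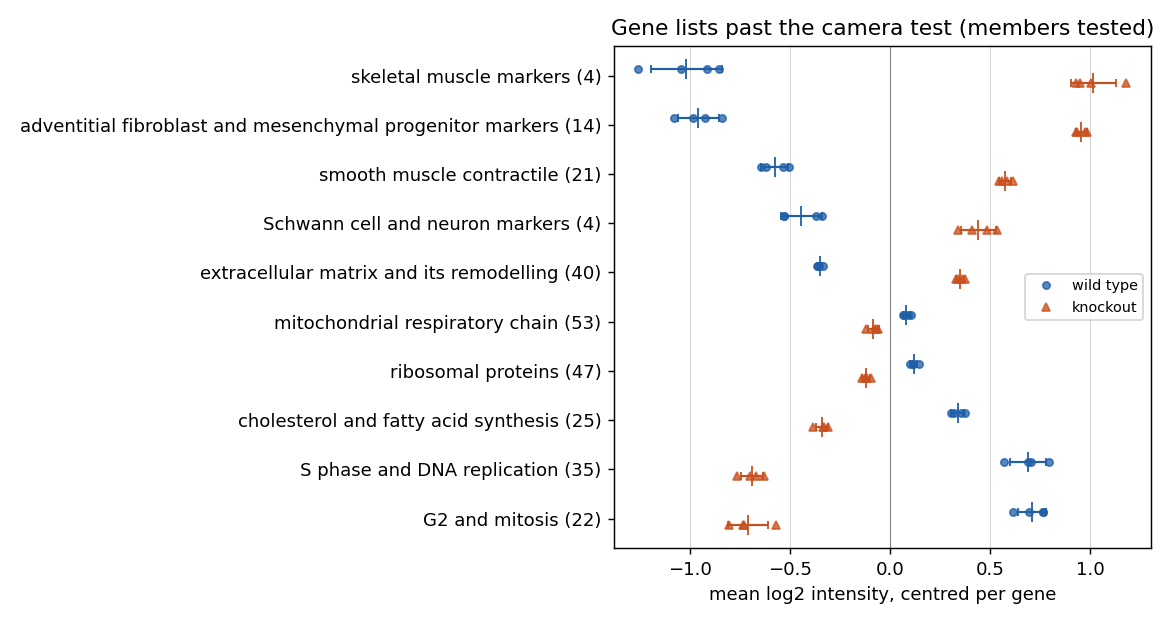
Mean log2 intensity of the members of each gene list that passed camera with a preset correlation, centred per gene on all 8 arrays (horizontal axis), in 4 wild-type arrays (circles) and 4 knockout-labelled arrays (triangles), with group means (ticks), 1 SD (bars) and the number of members tested in brackets. The genotypes do not overlap in any of the 10 lists, and the 35 replication genes lie between 0.57 and 0.79 in wild type and between -0.76 and -0.63 in knockout.

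The lists of calcium and growth factor genes did not pass camera, which compares a list with the other genes. The mean per array of the PDGF list was nevertheless 0.23 higher in knockout on the log2 scale (exact two-sided permutation p = 0.02857), or 0.14 without Igf1, with a median over its members of 0.053. That of the RGS list was 0.74 higher, but this rested on Rgs16, and the difference was -0.25 over the other 5 genes (exact two-sided permutation p = 0.02857 for both). Of 20 genes of calcium handling, 7 rose and 4 fell (camera adjusted p = 0.9303). Cacna1g, a T-type calcium channel, was at least 3.99-fold higher and the store-operated channel gene Orai1 was 1.59-fold higher, while the inositol trisphosphate receptor Itpr3 was 3.30-fold lower and the sodium-calcium exchanger Slc8a1 was 1.94-fold lower. Of 19 genes of calcineurin and NFAT signalling, 5 rose and 4 fell (camera adjusted p = 0.9303), with the calcineurin regulator Rcan2 6.87-fold lower, Nfatc4 3.40-fold higher and Nfatc1 1.54-fold lower. All 6 tested RGS genes passed, 2 higher and 4 lower (camera adjusted p = 0.7642), and beside Rgs16 these included Rgs3, 2.94-fold higher by its brightest probe but not by all of its 3 probes, and Rgs10, 1.84-fold lower. Of 27 genes of PDGF receptor and kinase signalling, 10 rose and 5 fell (camera adjusted p = 0.2812), with Igf1 5.86-fold, Egfr 4.34-fold and Pdgfra 1.88-fold higher. Of 29 immediate early genes, 14 rose and 4 fell (camera adjusted p = 0.1166), with Plk2 4.03-fold and Dusp1 3.52-fold higher and Arc 5.12-fold lower.

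Inflammatory and stress genes also moved both ways. Of 27 chemokine, cytokine and NF-kappaB genes, 9 rose and 9 fell (camera adjusted p = 0.5757). Ccl11 was at least 11.9-fold higher and Icam1 was 6.65-fold higher, while Cxcl12 was 6.60-fold lower. Of 28 interferon-stimulated genes, 12 rose and 5 fell (camera adjusted p = 0.2142), with Irgm1 2.85-fold higher and Ifi27l2a 3.34-fold lower. Of 25 genes of glycolysis and hypoxia, 7 rose and 10 fell (camera adjusted p = 0.7642). Adm, which encodes the vasodilator adrenomedullin, was 16.6-fold higher, and Egln3 was 2.08-fold lower. Of 24 genes of heat shock and oxidative stress, 5 rose and 7 fell (camera adjusted p = 0.7642), with Hspb1 2.51-fold higher and Gsta4 5.69-fold lower. Of 31 genes of the unfolded protein response, 8 rose and 9 fell (camera adjusted p = 0.7642). Chac1 (log2 change 1.24) and the kinase Eif2ak3 (2.04-fold) were higher, and Ddit4 and Psat1 were lower. Of 32 p53 targets and apoptosis genes, 13 rose and 6 fell (camera adjusted p = 0.2812). Bbc3 was 2.94-fold lower and Gadd45b was also lower, while Plk3 and Gadd45g were higher.

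In all, 10 of 26 lists passed camera with a preset correlation, 5 higher and 5 lower, 0 passed with an estimated correlation and 24 passed fry. Other groupings of the arrays gave 8 to 11 lists where they exchanged 1 array of each genotype, and 0 to 2 where they exchanged 2. Counts adjusted over the list alone differed for 3 lists only, with 1 respiratory chain gene, 10 chemokine genes and 4 skeletal muscle markers higher. The mean per array separated the genotypes for 18 of the 26 lists, these 10 and 8 that did not pass camera (exact two-sided permutation p = 0.02857, the smallest that 4 arrays against 4 can give). Without the member of largest change, chosen after the data were seen, these 10 lists kept separation and direction. Of the others, 7 turned in sign (calcium handling, calcineurin and NFAT, RGS, glycolysis, heat shock, endothelial and sex chromosome lists). The chemokine and heat shock lists no longer separated (p = 0.1714 and 0.8286, exact permutation), while the calcium handling, calcineurin and NFAT, glycolysis and immediate early lists did (p = 0.02857 each, exact permutation), at differences of -0.12, 0.11, -0.15 and 0.39. For calcium handling, calcineurin and NFAT, RGS, chemokine and glycolysis lists and the sex chromosome genes, the median, the mean and the test differed in sign.

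Genes near Atp2b4 were compared with the rest, because a knockout allele can carry flanking DNA of another strain. Within 25 Mb of Atp2b4 on its chromosome, by the gene order of the GRCm38.p6 annotation, 59 of 92 tested genes passed (64.13%), against 57.51% of the other genes (odds ratio 1.32, 95% confidence interval 0.846 to 2.09, Fisher's exact two-sided p = 0.2431). The difference in shares was not past the threshold. Rgs16 and Lhx9 lie within this window.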

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

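Of the tests in this part, those of the other splits of the arrays had their prediction written before their result was seen. The others were chosen after the results were seen, except that the share of called genes near Atp2b4 was planned before the data were examined, with its prediction written afterwards. The real split of the 8 arrays gave 4781 genes past the threshold. Of the 35 splits into 4 and 4, 1, the real one, gave as many, with 0 genes as the highest of the others. A share of 1 in 35 is the smallest that this test can give. Every other split mixes the genotypes, so the test cannot tell genotype from any other difference between the groups. For the number of gene lists, 5 of the 35 splits gave at least the real value of 10, and the highest of the others was 11. By the prediction chance was thus not excluded. The 16 splits that exchanged 1 array of each genotype still parted 3 arrays of each and gave 8 to 11 lists. The 18 that exchanged 2 gave 0 to 2. Splits of the first kind still carry part of the genotype difference, so the count cannot decide how many lists a random grouping gives.

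Single arrays stood far from the other 3 of their genotype in 17 of 302 groups of 4 arrays tested over named genes and lists (5.63%), where chance flags about 1 in 20. In knockout replicate 4, Dcn had a log2 value of 14.24 against 14.1 to 14.12 in the others and Eln had 6.20 against 5.89 to 5.94. In knockout replicate 1, Casp1 had 11.78 against 11.63 to 11.66 and Dusp1 had 13.59 against 12.84 to 12.91. In knockout replicate 2, Ramp3 had 5.96 against 5.39 to 5.48, Kif2c had 5.50 against 5.98 to 6.03, Igf1 had 10.2 against 10.02 to 10.04 and Ifit3 had 10.22 against 9.56 to 9.61. In knockout replicate 3, Nqo1 had 9.47 against 9.32 to 9.33. In wild-type replicate 1, Luzp2 had 8.88 against 9.33 to 9.37, Mvd had 8.71 against 8.46 to 8.48 and Cd14 had 8.39 against 7.85 to 7.94, and the mean of the p53 and apoptosis list had 0.046 against -0.061 to -0.046. In wild-type replicate 3, Myc had 6.55 against 6.07 in each of the others, the calcium handling list had 0.028 against -0.020 to -0.013 and the endothelial list had 0.135 against -0.061 to -0.042. In wild-type replicate 4, Ndufa4 had 14.21 against 14.19 in each of the others.

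The first pattern weighed is the fall of replication and mitosis genes in cells that were sorted for early G1. Background correction and normalization are argued against as the whole cause, since the smallest fall of either list's median under the 5 other corrections and normalizations was -1.17, although the mitosis median was -0.83 over more members without the filter on dim probes. More dividing cells inside the wild-type gate were predicted to lower both lists in knockout by about the same ratio. This assumes that replicating and mitotic cells entered the gate alike, which was not checked. The medians of the replication and mitosis lists differed by -0.136 (permutation p = 0.317 across genes, which are not independent replicates). That does not show that they are equal. A gate that differed and slower cycling within G1 thus cannot be told apart with RNA of whole sorted samples. An effect of PMCA4 on the cell cycle stays open and untested.

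The second pattern is the rise of adventitial fibroblast markers, whose median of 2.04 was 0.74 without the filter on dim probes. A lower share of smooth muscle cells in the knockout samples would by itself lower contractile genes. Their median log2 change was 0.7335, above 0 with no overlap between the genotypes, or 0.49 without the filter on dim probes. That argues against a lower share with levels per cell unchanged. It does not exclude a lower share beside a rise per cell, which RNA of whole samples cannot tell apart. A different position of origin of the cultures along the vessels was tested with homeobox genes, many of which mark position in the body, by a list of families that was itself written after Shox2, Lhx9 and other homeobox changes had been seen and was revised from a shorter one. Without Shox2 and Lhx9, 11 of 52 homeobox genes had a fitted change of at least 2-fold, against 11.2% of other genes (odds ratio 2.137, 95% confidence interval 0.987 to 4.25, Fisher's exact two-sided p = 0.0423), but with genes not above background in one genotype at their bound these were 9 of 52 (odds ratio 1.87, 0.798 to 3.90, p = 0.101). With both genes included the fitted odds ratio was 2.525 for these families and 4.15 for the shorter list, so it also depended on the families, and a different origin cannot be told apart from a change within the cells due to genotype, which stays open and untested.

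The third pattern is a cluster of large changes near Atp2b4. Within 25 Mb, 5 of 92 genes had a fitted change of at least 8-fold (5.43%), against 0.865% elsewhere (odds ratio 6.58, Fisher's exact two-sided p = 0.00149), namely Rgs16 and Prelp, which were higher, and Inhbb, Ptprv and Lhx9, which were not above background in one genotype and are bounded at 10.2-fold and 5.89-fold higher and 4.99-fold lower, and with such genes at their bound 3 of 92 remained (odds ratio 4.65, p = 0.03119). The call was lost under normexp with an offset of 50 (odds ratio 5.50, Fisher's exact p = 0.05714) and without wild-type replicate 4 (3.81, p = 0.05014), the value was 4.18 (p = 0.04027) without wild-type replicate 1, windows of 10 and 50 Mb gave 6.71 (p = 0.0125) and 5.59 (p = 3.78e-05), and the planned comparison of called shares gave an odds ratio of 1.321. Of windows of that width around tested genes, 0.639% held as large a share (1.18% with dim genes at their bound), for a size limit chosen after the changes were seen. Windows around neighbouring genes overlap and can hold the same large changes, those of this cluster included. That share is therefore not a chance rate, and chance location stays open. Probes that match the C57bl6 sequence but not another strain's would lower signal in knockout. If the probes are of that kind, which was not checked, this argues against mismatch for the 4 genes that were higher. For Lhx9, whose 2 tested probes both fell, mismatched probes stay open. Flanking DNA of another strain that alters expression is a candidate explanation and cannot be told apart from an effect of PMCA4 by the planned share, since genotype and flanking DNA travel together.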

How the results depend on the processing

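The minimum fold of 1.5, the 8-fold limit near Atp2b4 and counts with dim genes at their bound were chosen after the data were seen, and all other alternatives in this part before. Under background, normalization, filter, spread, weight and probe alternatives and with each array left out, genes past the threshold numbered 4257 to 4996, 44.02% to 50.89% of them higher, and 3713 passed an adjusted p of 0.01. The share higher was 44.02% to 44.72% without 1 knockout array and 47.66% to 48.11% without 1 wild-type array. The filter still asked for 4 arrays there, so genes above background only in the genotype that lost an array could not pass. Median scaling on all 8 arrays gave 44.39%. A log2 change of at least 1 left 933 genes (486 higher, 447 lower), or 842 (434 higher, 408 lower) with dim genes at their bound, and the minimum fold of 1.5 left 1110 (549 higher, 561 lower), fewer by construction. Without 1 array at a time, the Atp2b4 log2 difference ranged from -0.016 (without knockout replicate 1, where its sign turned) to 0.189 (without knockout replicate 3), past the threshold in none. With an estimated correlation, 0 lists passed. Of the 10 lists, 8 were kept under every other alternative, and the Schwann cell and neuron and the skeletal muscle markers were lost without the filter on dim probes (adjusted p = 0.4213 and 0.1375). The skeletal muscle list was tested in 17 alternatives, against 20 for each other list, since elsewhere it had fewer than 3 tested members. The share of called genes near Atp2b4 stayed short of the threshold under each alternative, and its odds ratio was 1.22 for 10 Mb and 1.04 for 50 Mb. The 8-fold changes there had an odds ratio of 6.71 (Fisher's exact p = 0.0125) for 10 Mb and 5.59 (p = 3.78e-05) for 50 Mb, but of 5.50 (Fisher's exact p = 0.05714) under normexp with an offset of 50 and of 3.81 (p = 0.05014) without wild-type replicate 4, and the cause was not tested. Of 118 called named genes, 117 kept direction and call under each background, normalization, filter, spread, weight, block, probe and left-out-array alternative in which they were tested (14 to 19 per gene), the exception being Cnp, and other thresholds were not applied to single genes. The log2 change of 23 of the 118 moved by over 1.5 times under some alternative, 19 of these under normexp with an offset of 50. Without the filter on dim probes the medians of the mitosis, matrix and fibroblast lists were -0.83, 0.27 and 0.74, over more members. Some calls were gained: the leukocyte and the chondrocyte lists with a detection p under 0.01 (adjusted p = 0.02072 and 0.0383), the latter also without wild-type replicate 2 (0.04962), the immediate early list without wild-type replicate 1 (0.03343), and Atp2b1 without wild-type replicate 2 (0.03283). With the replicate number as a block, 4609 genes passed, 4470 of them shared. Deviations of same-numbered arrays correlated at 0.087, 0.023, -0.029 and 0.010, and those of differently numbered arrays at -0.084 to 0.088. Of 4 wild-type arrays, 2 correlated best with their own number. These values do not decide whether the numbers pair the arrays. Of lists and genes that did not pass, sign changes were not counted. The slide as a block was not run, because the column headers used here carry no slide. Signal over background limits the folds of genes dim in one genotype to lower bounds, and these bounds hold for the main background correction and normalization only.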

Other observations

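Homeobox genes were not among the lists fixed in advance, and those named here were chosen after their values were seen. Beside Shox2 and Lhx9, the forebrain and limb factor Dlx1 (log2 change -2.48), Otx2 (-2.47), Irx3 (-1.67) and Irx5 (-1.42) were lower in knockout, Otx2 not above background there and at least 3.11-fold lower. Meox2 (2.55), Hoxd4 (2.38) and Hoxa7 (2.25) were higher by the fit and were not above background in wild type, which bounds them at 2.69-fold, 2.73-fold and 3.73-fold or more. Satb1 (1.53) and Hoxb5 (1.07, detected on 3 wild-type arrays) were also higher, as were Barx1 and En1, which were not above background in wild type and were at least 1.47-fold and 1.67-fold higher. In all, 32 of 54 tested homeobox genes passed the threshold, a share near the 57.59% of all genes tested. A fitted change of at least 2-fold was seen in 13, or 11 with genes not above background in one genotype at their bound.

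Some imprinted genes, also chosen after their values were seen, changed in both directions. Igf2, a fetal growth factor, was 4.18-fold lower in knockout (limma adjusted p = 1.61e-07), while Dlk1 was at least 2.35-fold higher and Grb10 was 2.31-fold higher. No list of imprinted genes was tested.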
